A study of Homo sapiens and Macaca mulatta and Mus musculus with 87 samples.

How the data were processed

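Pachytene spermatocytes, the cells in meiotic prophase, and round spermatids, the haploid cells that follow meiosis, were sorted from testes of human, rhesus macaque, mouse, bull, opossum and chicken by sedimentation at unit gravity (StaPut). Per the labels, purity was above 95% by phase microscopy, except in opossum 2, where it was 89 to 90%. Each cell preparation was split for RNA-seq and for chromatin immunoprecipitation with sequencing (ChIP-seq) of H3K4me3, a mark of active promoters, and H3K27me3, the mark of Polycomb repression, with input chromatin as the control. Human had 3 donors, rhesus and opossum 2 individuals each, mouse 2 preparations, and bull and chicken 1 preparation each, the chicken one pooled from 3 animals. The series text gives 1 mouse replicate and the sample labels show 2, which were followed. The labels do not say that each mouse preparation came from 1 animal, so p-values in mouse measure the spread between preparations. The round spermatid input of human donor 3 was not analysed here. In mouse, both the H3K27me3 antibody and the RNA and ChIP library kits differed between the 2 preparations per the labels, and human RNA was prepared with another kit than RNA of the other species. No level is compared between species by a test, because species, kit and annotation cannot be told apart.

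The ChIP files hold raw read counts per Ensembl gene as deposited, with a scaled column beside them. Per the submitters' processing notes, the tools for these files were Bowtie 1.1.1, TopHat2 2.0, MACS 1.4 and HTSeq, and the builds were hg19 for human, mm10 for mouse and galGal4 for chicken. The role of each tool, the other builds and the window counted for each gene are not given in the sources used here. "Window" below stands for the region the authors counted for a gene. The deposited scaled signal was the raw count times 1 constant per library and was not used further. The RNA files hold FPKM per Ensembl transcript as deposited, made with Cufflinks 2.2 per the submitters' processing notes. FPKM values were summed per gene. They keep no read depth, so no count test was run on RNA. Counting by strand is not stated for the ChIP or RNA files, so an antisense gene, a pseudogene or a small RNA gene inside a host can share reads with its partner.

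Human gene identifiers were matched to symbols, of which 52168 of 63651 in the RNA files and 51959 of 57736 in the count files had one. Several identifiers of a symbol were summed in RNA, and the window with the most H3K4me3 was kept in the count files. Chromosome and gene type came from the RefSeq annotation of a later assembly than hg19, so no coordinates are printed. The tables used here do not pair identifiers of the other 5 species with symbols. Gene lists were therefore tested in human alone, and the comparisons planned across species by symbol could not be computed. These were the genes with both marks and low RNA in all 6 species, and the genes whose RNA stage effect differs between human and mouse.

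Total counts per library were 947490 to 17126870 for H3K4me3 (median 6356938.5 over 22 libraries), 1013585 to 8585805 for H3K27me3 (median 3175794 over 22) and 431352 to 7031463 for input (median 2367923 over 21). Windows with fewer than 10 input reads were left out of the calls of marks. Enrichment was the log2 ratio of CPM in the immunoprecipitate to those in the input pooled over the replicates of a species and stage, with 0.5 reads added. It was expressed over a background level, the 20th percentile of windows for H3K4me3 and the median for H3K27me3. A window was called marked at 4-fold enrichment for H3K4me3 and 2-fold for H3K27me3. A gene with both marks in every library of both stages, and under 5 FPKM in every RNA library, was called bivalent and low. These limits are conventions, and a share of marked windows depends on depth, pull-down and input. Each mark was pulled down separately from many cells, so whether both marks lay on the same chromatin or in the same cells was not measured. Fixed gene lists were tested for bivalent and low genes with Fisher's exact test (one-sided, greater) over the usable human windows, with Benjamini-Hochberg (BH) adjustment over the lists. This test replaces the planned one over all species.

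Round spermatids were compared with pachytene spermatocytes within each replicated species. RNA was tested with limma 3.58.1 with a trend, on log2(FPKM + 1), over genes with a mean of at least 1 FPKM. Fold changes on this scale understate the change of low genes. ChIP counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM, its default filter on low counts). Adjusted p-values are BH values over all genes of a test, with a threshold of 0.05. The same-numbered samples of the 2 stages came from the same donor or animal, so the numbers pair the samples, and the fit with the individual as a block is given where it changes a call or moves a count by over 1.5 times. Deviations from the stage mean correlated across genes between the 2 stages of a donor at 0.797, 0.437 and 0.498 for human RNA, 0.200, 0.211 and -0.0106 for human H3K4me3, and 0.0640, 0.0912 and 0.0258 for human H3K27me3. The same correlation for RNA was 0.437 in rhesus, 0.793 in mouse and 0.592 in opossum. Gene lists were tested against all other genes with limma's camera, with a preset correlation of 0.01 and again with an estimated one, where at least 5 members were tested.

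The rule for genes named was fixed before the data were examined. It took the 10 largest rises and falls past the threshold with non-overlapping stages, leaving out uncharacterised symbols and Y-linked genes, the 4 members of each list with the largest change, and 5 stage markers. The result of 1 gene that this rule selects is not reported here. For human RNA the rule was applied to the blocked fit, because the fit without the block called 1 gene; this was decided after the counts were seen. For bivalent genes the 10 with the highest H3K27me3 were taken in human alone. The lists held HOX clusters, developmental transcription factors, developmental signalling, meiotic prophase, spermiogenesis, piRNA and germ granule, Polycomb and H3K27 demethylases, H3K4 methylation machinery, proteasome and ribosomal proteins. Lists of other cell types held spermatogonia, Sertoli, Leydig, peritubular myoid, macrophage and immune, endothelial and erythroid markers. All were fixed before the data were examined.

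The tests were tested on simulated data made from the real libraries, with up to 100 genes changed by each of 1 and 2 log2 units. In human H3K4me3 (47986 genes run) 18.8% and 95.6% of these were recovered, and in human H3K27me3 (48605 genes) 35.5% and 97.9%. In human RNA (19503 genes) the fit without the block recovered 0 and 0%, and the fit with the block 19% and 86%, with 21 false calls of 126. In rhesus RNA (12777 genes) the values were 0 and 29% without the block, and 53% and 100% with it, with 32 false calls of 185. In mouse both RNA fits (19344 genes) recovered 0 and 0%, and H3K27me3 (22550 genes) 0 and 1.14%. In opossum RNA (11138 genes) the values were 1% and 24% without the block, and 26% and 88% with it, with 2 false calls of 116. Alternatives covered the pseudocount (0.1), the filter on low values, quantile normalization, DESeq2 1.42.0, RLE size factors, library totals, other mark limits, the block and leaving out each library. Work was done in R 4.3.3 and Python 3.11.15.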

Results

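The series profiled male germ cells of 6 species at 2 stages, to ask which genes carry both the activating mark H3K4me3 and the repressive mark H3K27me3 at their promoters while their RNA is low, a state called poised or bivalent. Pachytene spermatocytes and round spermatids were each measured by RNA-seq and by ChIP-seq of both marks with an input control. The samples came from 3 human donors, 2 individuals each of rhesus and opossum, 2 mouse preparations, and 1 preparation each of bull and chicken. In total 22 H3K4me3, 22 H3K27me3 and 21 input libraries entered, with median totals of 6356938.5, 3175794 and 2367923 reads counted over genes. The shallowest H3K4me3 library was that of human donor 1 pachytene spermatocytes, with 947490 reads, and the shallowest input was in mouse, with 431352. RNA values are FPKM, whose read depth is unknown. Values are mean ± SD over individuals or mouse preparations, and bull and chicken have no replicate.

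Genes of known stage were looked at first. PRM1 (ENSG00000175646) and TNP1 (ENSG00000118245), which encode the protamine and transition protein that replace histones in spermatids, were higher in round spermatids of all 3 donors. PRM1 stood at 829 ± 318 FPKM in pachytene spermatocytes and 4259 ± 1490 in round spermatids (n = 3), and TNP1 at 625 ± 449 and 3461 ± 1886. PIWIL1 (ENSG00000125207), the Argonaute protein that binds pachytene piRNAs, was lower in round spermatids of all 3 donors, at 445 ± 158 and 122 ± 85.3 FPKM. In limma with the donor as a block the BH-adjusted p was 0.00427 for PRM1, 0.00429 for TNP1 and 0.00558 for PIWIL1; without the block it was 0.0567, 0.0871 and 0.108. SYCP3 (ENSG00000139351) and SYCP1 (ENSG00000198765), proteins of the synaptonemal complex that holds paired chromosomes, did not pass. SYCP3 was at 158 ± 59.8 and 98.3 ± 18.4 FPKM (limma with the block, adjusted p = 0.0557), lower in round spermatids of all 3 donors. SYCP1 was at 82.6 ± 18.8 and 92.2 ± 25.8 FPKM (limma with the block, adjusted p = 0.702), and its log2 difference of 0.14 became -0.19 without donor 2.

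Human RNA of round spermatids differed from that of pachytene spermatocytes in genes of sperm formation, most of which rose, and in genes of the piRNA pathway, many of which fell. Of 47 spermiogenesis genes measured, 36 rose and 1 fell with the donor as a block, 37 and 2 adjusted over the list alone, with a median log2 change of 1.94. IZUMO1, the sperm protein that binds the egg, went from 4.48 ± 1.17 to 30.2 ± 4.17 FPKM (log2 change 2.52, SE 0.20), and GAPDHS, the glycolytic enzyme of the sperm tail, from 37.8 ± 38.3 to 204 ± 184 (2.51, SE 0.22). ACRV1, an acrosomal protein, went from 25.2 ± 24.5 to 134 ± 117 FPKM (2.43, SE 0.18). Of 20 piRNA and germ granule genes, 10 fell and 1 rose, and 10 fell adjusted over the list alone. They included PIWIL1 (log2 change -2.09), TDRD5 (-1.88), the small RNA methyltransferase HENMT1 (-1.52) and TDRD1 (-1.37). In limma's camera with its preset correlation, the adjusted p was 1.11e-07 for spermiogenesis and 3.95e-06 for the piRNA list. Both calls were lost with an estimated correlation (adjusted p = 0.629 and adjusted p = 0.482). The median change of the tested genes was 0.25, and -0.04 after quantile normalization, under which 36 spermiogenesis genes rose and 3 fell, and 2 piRNA genes rose and 10 fell. With the block and without donor 1, 28 of 47 spermiogenesis genes rose and 0 fell, and 0 of 21 piRNA genes rose and 2 fell.

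Over all 19503 human genes tested, limma without the block called 1 gene, a gene without a symbol in the tables used here (ENSG00000272220) that fell from 44.6 ± 21.0 FPKM to about 0. At an unadjusted p under 0.05 it counted 4866. With the donor as a block 6438 genes passed, 4730 up and 1708 down. After quantile normalization with the block the split was 3122 up and 3237 down. Stages did not overlap in 31.5% of genes, where chance gives 10%. With the block and without donor 1, 2 or 3, the number was 1435, 4296 or 5964. Without the block and without donor 1 it was 1827 in limma, and without donor 2 or 3 it was 0, with 1706 and 2917 at an unadjusted p under 0.05.

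Among the largest rises with the block were PTCH1, the Hedgehog receptor, from 3.51 ± 1.32 to 29.5 ± 12.2 FPKM (log2 change 2.70, SE 0.24), and APOE, the lipid carrier, from 6.57 ± 1.36 to 46.8 ± 10.6 (2.65, SE 0.20). LRRTM3, a synaptic adhesion protein, went from 1.39 ± 1.15 to 15.1 ± 4.05 (2.83), and BANF2 from 8.56 ± 8.62 to 49.1 ± 25.1 (2.65). HMCN2 and the antisense gene EFCAB14-AS1 rose by 3.00 and 2.96. SNORD13, a small nucleolar RNA, and IQCJ-SCHIP1-AS1 were listed at 0 in all 3 pachytene libraries and passed the test, at 882 ± 1056 and 13.1 ± 7.14 FPKM in round spermatids. FPKM is less reliable for a gene as short as SNORD13. The largest fall among genes with a symbol was in CETN3, a centrin of the centriole, from 783 ± 104 to 111 ± 68.0 FPKM (log2 change -3.01, SE 0.37). LDHAL6B, a testis lactate dehydrogenase, fell from 139 ± 44.0 to 21.9 ± 11.8 (-2.68), SLC2A14, a testis glucose transporter, from 236 ± 175 to 35.9 ± 11.5 (-2.48), and POU5F2, a POU domain factor, from 50.2 ± 28.1 to 7.77 ± 2.54 (-2.45). CCDC112 (-2.73), ELFN2 (-2.51), ANKRD30BL (-2.49) and the noncoding STIM2-AS1 (-2.84), LINC00964 (-2.58) and SPATA8-AS1 (-2.49) completed the 10. The adjusted p of these genes in limma with the block lay between 0.00424 and 0.0115. Rises of similar or larger size were seen in HBB of red cells and ACTA2 of smooth muscle, given with markers of other cells below. Whether the rises here and of the signalling genes below came from spermatids or from other cells in the fractions was not tested.

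Genes of meiosis and of chromatin moved both ways. Of 42 meiotic prophase genes, 14 rose and 6 fell (15 and 9 adjusted over the list alone; 10 and 12 after quantile normalization with the block). The cohesin subunit RAD21L1 rose by 1.91, TEX15 by 1.76 and RAD51AP2 by 1.67, and TEX14, a protein of the intercellular bridges between germ cells, fell by 1.81. Of 24 Polycomb and H3K27 demethylase genes, 6 rose and 1 fell, 2 and 3 after quantile normalization. BMI1, a core member of Polycomb repressive complex 1, went from 31.1 ± 7.13 to 106 ± 33.2 FPKM (1.72), JARID2 from 5.97 to 13.3 (1.08) and CBX2 from 1.84 to 4.66 (0.95). RBBP4, a histone chaperone shared by PRC2 and other complexes, went from 270 ± 142 to 60.0 ± 11.0 (-2.05). Of 14 genes of H3K4 methylation 3 rose and 1 fell, 2 and 2 after quantile normalization: the methyltransferases KMT2C (1.07) and KMT2A (1.00), the demethylase KDM5C (1.05), and the demethylase KDM5B (-0.68). With the block and without donor 1 the rises and falls were 5 and 1 for meiotic, 1 and 1 for Polycomb and 0 and 0 for H3K4 methylation genes. None of these 3 lists passed camera. Over all 19503 genes tested 4730 rose and 1708 fell with the block, and the Polycomb and H3K4 methylation counts are close to these shares.

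Developmental genes were mostly below the expression filter, and few of those above it passed. Of 38 developmental transcription factors tested 4 rose and 4 fell, 2 and 5 after quantile normalization. LMX1A went from 0.473 to 2.94 FPKM and SHOX2 from 1.19 to 4.62 (1.36), against POU4F2 from 6.45 to 0.853 (-1.87). Of 8 HOX genes HOXA5 fell, from 3.46 ± 0.990 to 0.303 ± 0.192 FPKM (-1.76), and the others did not pass (2 fell after quantile normalization). Of 14 signalling genes 5 rose and 0 fell, 6 and 1 adjusted over the list alone, and 3 and 1 after quantile normalization. They included PTCH1, the secreted Wnt modulators SFRP4 (1.97) and SFRP1 (1.18), and the guidance cue SLIT3 (1.35). Of 33 proteasome genes 3 rose and 1 fell, and of 58 ribosomal protein genes 1 rose, RPLP2, with 0 and 0 for both lists adjusted over the list alone. With the block and without donor 1, 2 of 18 signalling genes rose, and 0 genes of the other 4 lists of this paragraph passed in limma. The camera test did not pass for developmental signalling (limma's camera, adjusted p = 0.163), nor for the other lists of this paragraph.

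Markers of other testis cells moved with the stage as well. All 6 peritubular myoid genes, of the contractile cells around the seminiferous tubules, were higher in round spermatids with the block, with a median change of 1.93 (5 after quantile normalization, 3 without donor 1). ACTA2, smooth muscle actin, went from 15.2 ± 4.64 to 102 ± 20.1 FPKM (2.70, SE 0.23), MYH11 by 2.51, TAGLN by 1.93 and CNN1 by 1.92. The preset camera adjusted p of limma was 6.31e-04 for this list, and with an estimated correlation the call was lost (adjusted p = 0.482). All 3 erythroid genes tested rose, among them HBB, the beta globin of red cells, from 3.38 ± 4.80 to 28.4 ± 18.5 FPKM (3.13, SE 0.31); without donor 1, 1 of the 3 passed. Of 7 Leydig markers 3 rose (IGF1 1.78, LHCGR 0.80, DLK1 0.76), 4 adjusted over the list alone, 1 after quantile normalization and 1 without donor 1. Of 8 Sertoli markers VIM rose (1.22) while SOX9 (-1.12) and CLU (-0.63) fell; without donor 1, 1 of 9 rose and 0 fell. Of 6 endothelial markers CDH5 rose (1.09), with 0 adjusted over the list alone and 0 after quantile normalization, and of 12 spermatogonia and 3 macrophage markers 0 passed in limma with the block.

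**Figure D1:**
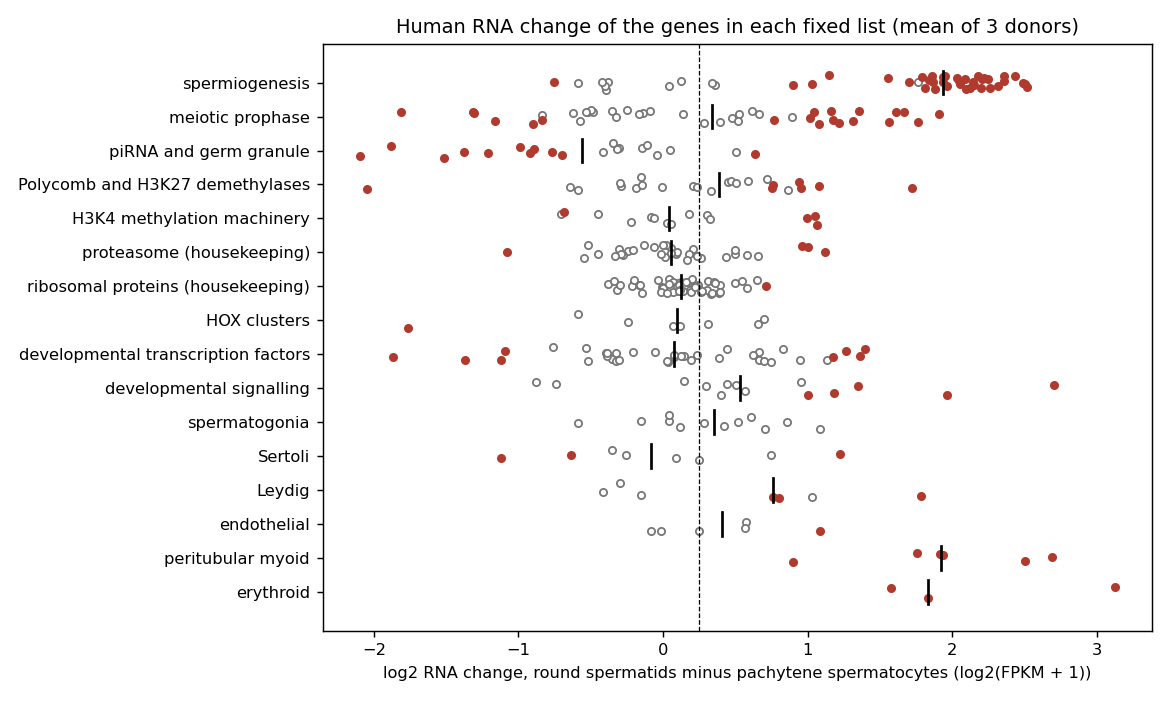
Log2 RNA change of each human list member from pachytene spermatocytes to round spermatids (log2(FPKM + 1), mean of 3 donors); filled points passed limma with the donor as a block, bars are list medians and the dashed line is the median of all tested genes. The spermiogenesis and peritubular myoid lists have medians of 1.94 and 1.93, and the piRNA list lies at -0.56.

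X-linked genes, which are silenced as the sex body forms in pachytene spermatocytes, were compared with autosomal ones. The median RNA change of 447 human X-linked genes was 0.86 ± 0.16 (n = 3), against 0.21 ± 0.02 for 15803 autosomal genes, and the difference was 0.83, 0.50 and 0.60 in the 3 donors. In round spermatids 90.4 ± 3.13% of X-linked genes were above their pachytene level, against 60.0 ± 2.16% of autosomal genes. Median FPKM of X-linked genes was 2.02 ± 0.450 in pachytene spermatocytes and 4.27 ± 0.545 in round spermatids, below the autosomal 6.17 ± 0.431 and 8.03 ± 0.372. The list passed limma's camera at the preset correlation (adjusted p = 1.94e-09), and the call was lost with an estimated correlation (adjusted p = 0.482). Without the filter on low values the difference shrank to 0.19, over more and lower genes. The share of windows with a mark was lower on the X for both marks, without a test of the difference: for H3K27me3 7.49 ± 0.483% against 20.9 ± 1.86% of autosomal windows in pachytene spermatocytes and 10.6 ± 2.52% against 23.9 ± 2.95% in round spermatids, and for H3K4me3 21.2 ± 12.1% against 30.4 ± 11.5% and 33.2 ± 2.03% against 40.9 ± 0.954%.

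In the other replicated species the size of the RNA difference between the stages was alike in the 2 rhesus animals and varied between the 2 mouse preparations and between the 2 opossums. The median log2 change was -0.29 in both rhesus animals, -0.08 and 0 in the 2 mouse preparations, and 0.04 and 0.06 in the 2 opossums. A 2-fold rise or fall on the log2(FPKM + 1) scale was seen in 0.790% and 1.01% of genes in opossum 1 and in 13.4% and 19.9% in opossum 2, in 22.1% and 18.6% in mouse preparation 1 and 19.6% and 8.79% in preparation 2, and in 13.4% and 21.5% in rhesus 1 and 11.4% and 21.7% in rhesus 2. In limma without the block 1 rhesus, 0 mouse and 0 opossum genes passed, of 12777, 19344 and 11138 tested, with 4257, 1654 and 562 at an unadjusted p under 0.05. The 2 mouse preparations differed in FPKM level. Summed FPKM of pachytene spermatocytes and round spermatids was 5273152 and 5724783 in preparation 1, against 652697 and 753644 in preparation 2. Between preparations Pearson's r across genes was 0.391 and 0.393 in the 2 stages, against 0.705 and 0.845 between stages within a preparation. The 0 mouse calls therefore do not show that the stages were alike. With the individual as a block 5657 rhesus genes passed (1985 up, 3672 down), 2735 mouse genes (2082 up, 653 down) and 560 opossum genes (122 up, 438 down). After quantile normalization with the block the splits were 2185 and 1798, 1535 and 950, and 178 and 543. That normalization moved the median of all tested genes from -0.31 to -0.07 in rhesus and from 0.00 to -0.14 in mouse. Each of these blocked fits rests on 2 individuals or preparations, which leaves little residual spread to measure. In simulated data the blocked mouse fit recovered 0% of the changed genes. The share of false calls among the rhesus and mouse genes is unknown. In bull 8.62% of genes were at least 2-fold higher in round spermatids and 1.35% lower, and in chicken 1.66% and 4.98%, with no replicate check.

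The question of poised genes was addressed by counting genes with both marks in every library of both stages and RNA under 5 FPKM. Whether both marks lay on the same chromatin was not measured. In human, bivalent and low genes were over-represented in the fixed lists of embryonic regulators, which hold a small part of the 1618 found. Of 149 developmental transcription factors with a usable window 83 were bivalent and low (55.7%), of 38 HOX genes 18 (47.4%) and of 67 developmental signalling genes 23 (34.3%), against 3.12% of all 51858 windows. Fisher's exact test (one-sided) gave BH-adjusted p of 5.51e-83, 7.53e-17 and 2.41e-17. Of 48 spermiogenesis, 41 meiotic prophase, 21 piRNA, 33 proteasome and 57 ribosomal protein genes 0 were in this state, whose limit of 5 FPKM lies below the median levels of these lists (24.2 to 112 FPKM). At any expression 6, 2, 0, 1 and 1 of them carried H3K27me3 in every library. Of 25 Polycomb genes 2 were (Fisher's exact test, adjusted p = 0.444), and 0 genes of H3K4 methylation. Among markers of other cells it was 3 of 14 Sertoli genes (Fisher's exact test, adjusted p = 0.0362, and 0.103 among protein-coding genes), 2 of 17 spermatogonia genes and 1 of 6 erythroid genes. For the Leydig, myoid, macrophage and endothelial lists it was 0.

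Named by their H3K27me3, the leading bivalent and low human genes included NKX6-2, HOXC5, WNT1, PRDM12 and POU3F3, factors of neural and axial patterning. Log2 enrichment over background at NKX6-2 (ENSG00000148826) in pachytene spermatocytes was 3.74 ± 0.38 for H3K4me3 and 3.96 ± 0.34 for H3K27me3 (n = 3), with 0.774 ± 0.570 FPKM, and in round spermatids 3.16 ± 0.17 and 3.69 ± 0.62, with 0.850 ± 0.538 FPKM. At WNT1 (ENSG00000125084) it was 2.89 ± 0.11 and 3.71 ± 0.33, then 3.48 ± 0.19 and 3.81 ± 0.53. At HOXC5 (ENSG00000172789) it was 2.67 ± 0.31 and 3.59 ± 0.18, then 3.29 ± 0.21 and 3.97 ± 0.48, and POU3F3 carried the most H3K4me3 of these 5, at 4.16 ± 0.69 in pachytene spermatocytes. GP1BB, GATA2-AS1, LINC01248 and the microRNA genes MIR3621 and MIR3663 completed the 10. Over all 149 developmental transcription factors the median H3K4me3 enrichment was 2.65 ± 0.30 in pachytene spermatocytes and 2.65 ± 0.14 in round spermatids, and that of H3K27me3 2.93 ± 0.27 and 3.24 ± 0.46. Of these factors 145 carried H3K27me3 in every library and 93 carried H3K4me3.

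In total 1618 human genes were bivalent and low, of which 832 are protein-coding, while 795 would be found if the marks in all libraries were independent before any limit on RNA and 2172 had both marks at any expression. The count depends on the limits: it was 4289 with a 2-fold and 142 with an 8-fold limit for H3K4me3, and 946 with RNA under 1 FPKM. Without donor 1 it was 2700. With protein-coding genes alone, and background levels set among them, it was 109.

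**Figure D2:**
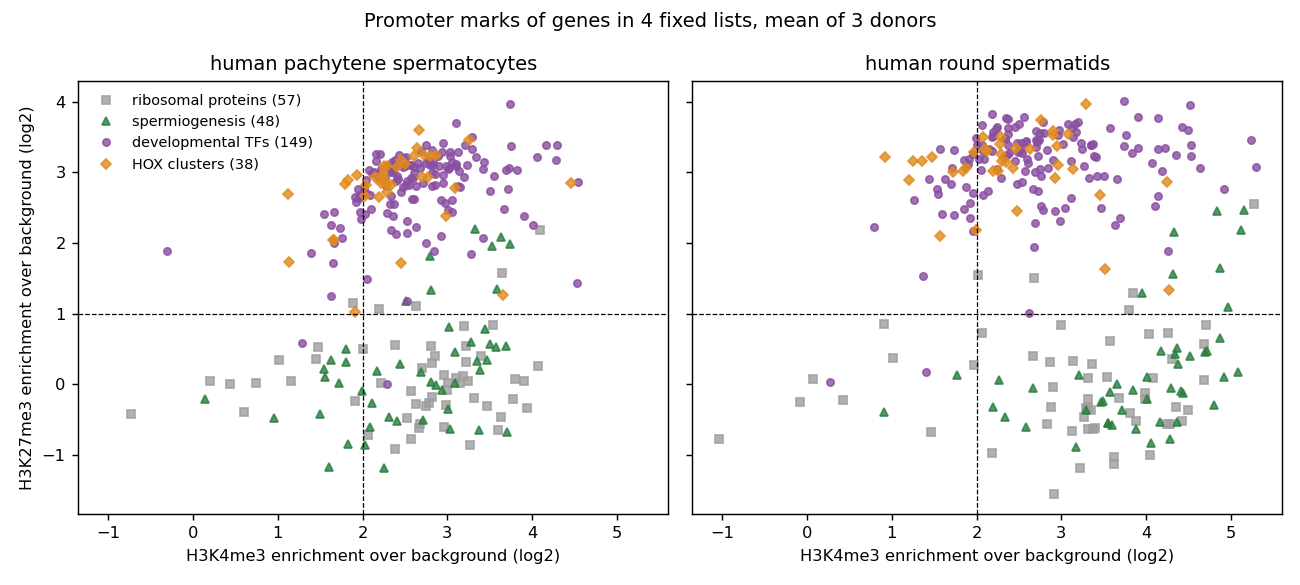
H3K4me3 against H3K27me3 enrichment of human genes in 4 fixed lists (log2 over background, mean of 3 donors), with dashed lines at the limits of 4-fold and 2-fold. Of 149 developmental transcription factors 145 carried H3K27me3 in every library, against 1 of 57 ribosomal protein genes.

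Bivalent and low genes were found in each of the other 5 species under the same limits. They numbered 1367 in rhesus (4.90% of usable windows), 1176 in mouse (3.41%), 435 in opossum (2.00%), 132 in bull (0.635%) and 31 in chicken (0.201%). In mouse the limit of 5 FPKM was applied to 2 preparations whose FPKM levels differed. Bull and chicken rest on 1 library per stage and mark, and their counts fell to 0 with the 8-fold H3K4me3 limit and rose to 811 and 537 with the 2-fold limit. Per library, windows with both marks exceeded the number for independent marks in human (means of 4576 against 2334 in pachytene spermatocytes, 5870 against 3594 in round spermatids) and rhesus (3021 against 1911, 3586 against 2318). In mouse pachytene spermatocytes they were 5133 against 4397 and 4561 against 3584 in preparations 1 and 2, and in round spermatids 6902 against 5590 and 2177 against 2494, below it in preparation 2. In opossum they were 1943 against 1945 and 3076 against 2508 in pachytene spermatocytes of animals 1 and 2, and 1060 against 966 and 1460 against 1827 in round spermatids. In bull (699 against 1275, 298 against 619) and chicken (108 against 334, 192 against 465) they lay below it.

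RNA levels were ordered by mark in every species and stage, from H3K4me3 alone through both marks to H3K27me3 alone. Genes with neither mark, the largest class, had no common place relative to H3K27me3 alone. Their mean of medians lay below it in both stages of human, rhesus and mouse, and above it in opossum, bull and chicken. In pachytene spermatocytes it was 0 FPKM in human, against 2.87 in chicken. In human pachytene spermatocytes the median was 6.52 ± 0.528 FPKM with H3K4me3 alone, 0.391 ± 0.130 with both and 0.0939 ± 0.0476 with H3K27me3 alone (n = 3), and in round spermatids 7.70 ± 0.985, 0.821 ± 0.0922 and 0.148 ± 0.0415. On the log2 scale, with 1 FPKM added, genes with both marks lay 2.44 ± 0.04 and 2.25 ± 0.09 units under those with H3K4me3 alone in human. In rhesus the difference was -2.79 ± 0.21 and -2.63 ± 0.28, in mouse -2.90 ± 0.27 and -2.65 ± 0.08, and in opossum -1.82 ± 0.37 and -2.07 ± 0.18 (n = 2 each). In bull it was -1.73 and -1.68, and in chicken -0.87 and -1.45. No test was run between species. The 108 chicken genes with both marks in pachytene spermatocytes had a median of 7.72 FPKM, against 15.0 with H3K4me3 alone, and with a 3-fold limit for H3K27me3 the difference was -0.32.

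**Figure D3:**
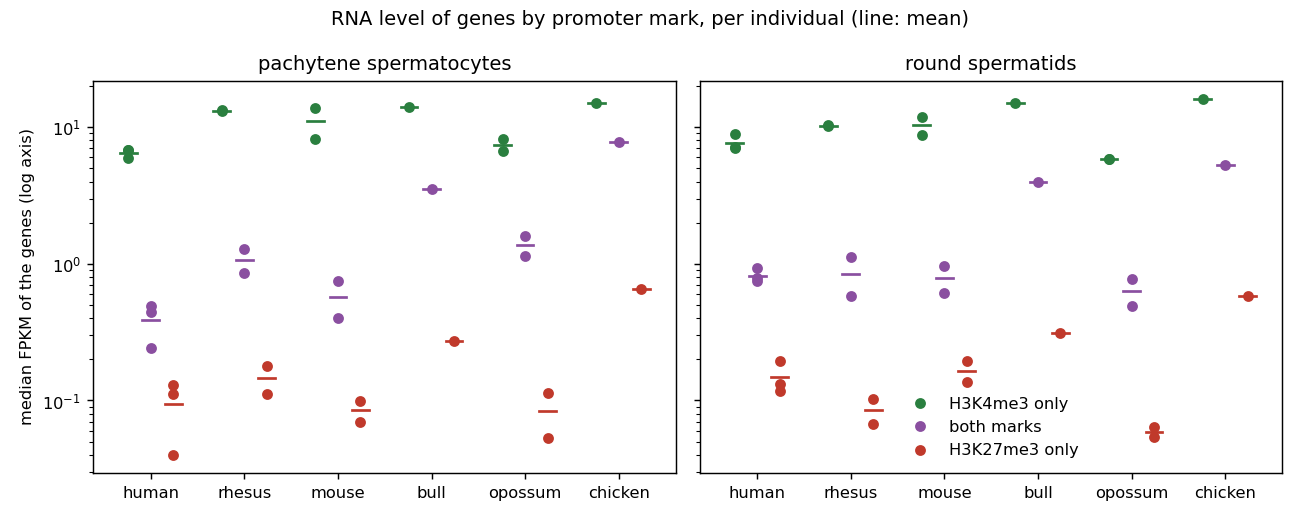
Median FPKM (log axis) of genes with H3K4me3 alone, both marks or H3K27me3 alone, with 1 point per individual and a line at the mean, for 6 species and both stages. In each species and stage the points are ordered from H3K4me3 alone to H3K27me3 alone, from 15.0 through 7.72 to 0.656 FPKM in chicken pachytene spermatocytes.

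H3K4me3 in human rose between the stages at genes of sperm formation. Of 48 spermiogenesis genes tested 30 rose and 0 fell (37 and 0 adjusted over the list alone), with a median log2 change of 1.15. AKAP4, the anchoring protein of the sperm fibrous sheath, went from 7.48 ± 4.60 to 27.4 ± 9.23 CPM (counts scaled to a common library size; log2 change 1.62, SE 0.31), FSCN3, a fascin of the testis, from 19.1 ± 10.5 to 62.3 ± 4.76 (1.58), SUN5, which ties the sperm head to the tail, from 20.8 ± 10.8 to 61.4 ± 8.64 (1.47) and ACTL7A, an actin-like protein of the sperm head, from 34.0 ± 13.4 to 98.1 ± 12.9 (1.47). Their edgeR adjusted p was between 0.0112 and 0.0113. Limma's camera gave the list an adjusted p of 4.16e-30 at the preset correlation and lost the call with an estimated one (adjusted p = 0.574). Without the donor 1 pachytene library, which stood apart with 15.0% of windows marked against 32.2% and 27.04% in donors 2 and 3, 34 spermiogenesis genes rose and 1 fell. Without the donor 2 round spermatid library edgeR called 0 windows in all, so that 0 of this list passed.

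Other groups moved less. Of 148 developmental transcription factors 5 rose, among them EVX1 (1.13), DLX6 (1.11), SHOX2 (1.05) and EVX2 (1.04), while the list as a whole had a median of -0.24, with 30 of 148 higher in round spermatids. Of 38 HOX genes HOXB1 rose (1.20), of 66 signalling genes EFNB3 (1.12), of 41 meiotic genes REC8 (1.21) and TEX15 (1.04), of 25 Polycomb genes the demethylase KDM6B (1.06), and of 14 genes of H3K4 methylation CXXC1 (0.93). PSMA6 rose of 33 proteasome genes (0.88), RPS2 (1.08) and RPS13 (0.94) of 52 ribosomal protein genes, CNN1 of 6 myoid genes (1.30) and CYP17A1 of 11 Leydig genes (1.05). Of the piRNA, spermatogonia, Sertoli, macrophage, endothelial and erythroid lists 0 genes passed in edgeR. With the donor as a block 5 developmental transcription factors rose and 3 fell, 1 HOX and 1 signalling gene fell beside the 1 that rose in each list, 5 meiotic, 2 Polycomb and 4 ribosomal protein genes rose, and CXXC1 no longer passed (edgeR adjusted p = 0.0502), leaving 0 genes of H3K4 methylation. Without the donor 1 pachytene library 8 developmental transcription factors rose and 7 fell, 7 meiotic genes rose and 2 fell, and 6 Polycomb genes rose. At the preset correlation limma's camera placed developmental transcription factors (adjusted p = 7.59e-04), signalling (0.0127), HOX (0.0205) and Sertoli genes (0.0205) below other genes. It placed ribosomal protein (0.00125), meiotic (0.00169), Polycomb (0.00902) and X-linked genes (0.0205) above them. With an estimated correlation all of these calls were lost (adjusted p = 0.574 for each).

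Over 48883 human windows tested edgeR called 2530, 2493 up and 37 down, and 3356 with the donor as a block, 3102 up and 254 down. Without the donor 1 pachytene library, which stood apart, the split was 4367 up and 800 down, so the number of falls depended on that library. With the block and without donor 1 the split was 4300 up and 751 down. Scaled by library totals alone the split was 1702 up and 175 down, with the median of all windows at -0.24 instead of -0.05. The largest rise was at PLN, the phospholamban gene, from 1.09 ± 0.472 to 5.74 ± 2.71 CPM (log2 change 2.59, SE 0.48, edgeR adjusted p = 0.0112). NME3, a nucleoside diphosphate kinase, went from 8.06 ± 2.91 to 26.3 ± 3.77 (1.60) and the noncoding RUNX2-AS1 from 30.3 ± 16.2 to 97.5 ± 20.2 (1.60). LINC02510 (1.78), KCNH7-AS1 (1.73), the small RNA gene SNORA65 (1.60) and the pseudogenes OR5H7P (1.64), CCDC74BP1 (1.64) and RPL17P43 (1.60) rose too. The 10 largest falls held 9 pseudogenes at low counts, NKAIN1P1 (-1.73), RNU7-116P (-1.67), TCF3P1 (-1.54), NOS2P4 (-1.52), HIGD1AP1 (-1.37), RNU6-1013P (-1.35), RNA5SP218 (-1.33), GBP1P1 (-1.27) and MRPL3P1 (-1.23), whose reads can be shared with near copies. With the block TCF3P1, NOS2P4 and MRPL3P1 did not pass (edgeR adjusted p = 0.0557, 0.0762 and 0.0970). The remaining one was OR51E2, an olfactory receptor gene, from 4.48 ± 1.09 to 1.45 ± 0.477 CPM (-1.39, edgeR adjusted p = 0.0233). Each library moved the count by over 1.5 times. It was 5167, 1391 or 1645 without the pachytene library of donor 1, 2 or 3. Without the round spermatid library of donor 1, 2 or 3 it was 554, 0 or 1532 in edgeR, the 0 standing beside 5519 windows at an unadjusted p under 0.05.

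For H3K27me3 in human few windows differed between the stages. In edgeR 4 of 49211 windows passed, all 4 higher in round spermatids, with 2639 at an unadjusted p under 0.05. They were FASTK, a mitochondrial RNA-binding protein, from 10.2 ± 2.33 to 26.1 ± 4.11 CPM (log2 change 1.37, edgeR adjusted p = 0.0147), RNU4-1, a gene of the spliceosomal U4 RNA with near copies, from 2.97 ± 0.779 to 9.65 ± 2.57 (1.64, edgeR adjusted p = 0.0202), and 2 genes with a clone name or no symbol. DESeq2 called 2. Developmental genes were higher in round spermatids as groups in the fit over 3 donors: 143 of 149 transcription factors (median 0.24), 38 of 38 HOX genes (0.24) and 63 of 67 signalling genes (0.19), though 0 of them passed singly in edgeR. This came from donor 1: the median change in enrichment over background was 1.19, -0.01 and -0.09 in the 3 donors for the transcription factors, 1.16, -0.08 and -0.18 for HOX genes and 0.98, -0.09 and -0.16 for signalling genes. Limma's camera at the preset correlation gave adjusted p of 2.52e-12, 3.74e-07 and 1.93e-05 for these lists, lost with an estimated correlation (adjusted p = 0.704 for each). Spermatogonia (0.00668), erythroid (0.0215) and meiotic genes (0.0243) lay above other genes by the same test of limma's camera, and ribosomal protein (0.0235) and H3K4 methylation genes (0.037) below, as adjusted p, and these too were lost (adjusted p = 0.704, and 0.439 for erythroid and meiotic genes). The rise was largest in donor 1 here too. The medians in the 3 donors were 1.04, -0.17 and -0.05 for spermatogonia, 0.86, 0.18 and -0.02 for erythroid and 0.30, 0.13 and 0.19 for meiotic genes. They were -0.24, 0.01 and -0.09 for ribosomal protein genes and -0.37, -0.27 and -0.02 for H3K4 methylation genes. Of windows with H3K27me3 in pachytene spermatocytes, 92.0%, 89.2% and 86.3% kept it in round spermatids in the 3 donors, and of windows with the mark in round spermatids 62.9%, 83.9% and 88.9% had it in pachytene spermatocytes.

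In the other replicated species H3K4me3 moved in both directions, with a split that depended on the libraries and the scaling. In rhesus edgeR called 3851 of 27463 H3K4me3 windows, 3422 up and 429 down, and with the animal as a block 3958 up and 1605 down, led by ENSMMUG00000008454 (log2 change 2.41) and ENSMMUG00000015205 (2.38), with ENSMMUG00000027144 (-2.86) and ENSMMUG00000013431 (-2.37) the largest falls. In mouse 2331 of 31573 passed, 2298 up and 33 down, and 4244 with the preparation as a block, 3453 up and 791 down. ENSMUSG00000079093 (4.41) and ENSMUSG00000097179 (4.15) rose most, and ENSMUSG00000089726 (-2.18) and ENSMUSG00000025733 (-1.69) fell most. In opossum 2728 of 21340 passed, 1206 up and 1522 down, and 6556 with the block, 3003 up and 3553 down. ENSMODG00000003252 (1.74) and ENSMODG00000025839 (1.68) rose most, and ENSMODG00000012234 (-2.27) and ENSMODG00000006367 (-2.18) fell most. With library totals alone the splits were 2415 and 3699 in rhesus, 2949 and 2383 in mouse, and 2030 and 1110 in opossum, and the rhesus median over windows moved from -0.08 to -0.48. Leaving out the mouse pachytene library 1 or the opossum round spermatid library 2 brought the edgeR count to 0, with 1670 and 1988 windows at an unadjusted p under 0.05. Without the mouse round spermatid library 1 the split was 2452 up and 2433 down.

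H3K27me3 fell at 368 and rose at 1 of 21560 opossum windows in edgeR, and at 1712 and 12 with the animal as a block. The edgeR count was 0 without the pachytene library 2, with 643 at an unadjusted p under 0.05, 15 without the round spermatid library 2 and 910 without the pachytene library 1. In rhesus 7 of 27683 windows rose, and 2793 passed with the block, 2439 up and 354 down, while edgeR with RLE size factors or library totals alone called 0, with 2364 and 1999 at an unadjusted p under 0.05, and DESeq2 called 100. In mouse edgeR called 0 of 24633, with 129 at an unadjusted p under 0.05, and DESeq2 called 0, with 128.

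The share of windows marked was also taken in each individual. In opossum H3K27me3 was on 23.5% and 26.8% of windows in pachytene spermatocytes and on 12.04% and 21.4% in round spermatids of animals 1 and 2, and 49.7% and 63.9% of marked windows kept the mark. In bull the share went from 20.9% to 10.05%, with 47.5% kept. In rhesus it went from 16.8% to 20.8% and from 20.6% to 22.0%, and in chicken from 11.2% to 13.4%, with 98.4% kept. In mouse preparation 1 it went from 26.9% to 30.01% and in preparation 2, made with another antibody, from 26.8% to 22.5%. For H3K4me3 the share was 15.0%, 32.2% and 27.04% in pachytene spermatocytes and 34.2%, 33.9% and 33.1% in round spermatids of the 3 human donors, and for H3K27me3 16.0%, 18.5% and 19.0%, then 23.4%, 19.7% and 18.4%. In mouse the H3K4me3 share went from 47.4% to 54.1% in preparation 1 and from 38.9% to 32.1% in preparation 2.

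**Figure D4:**
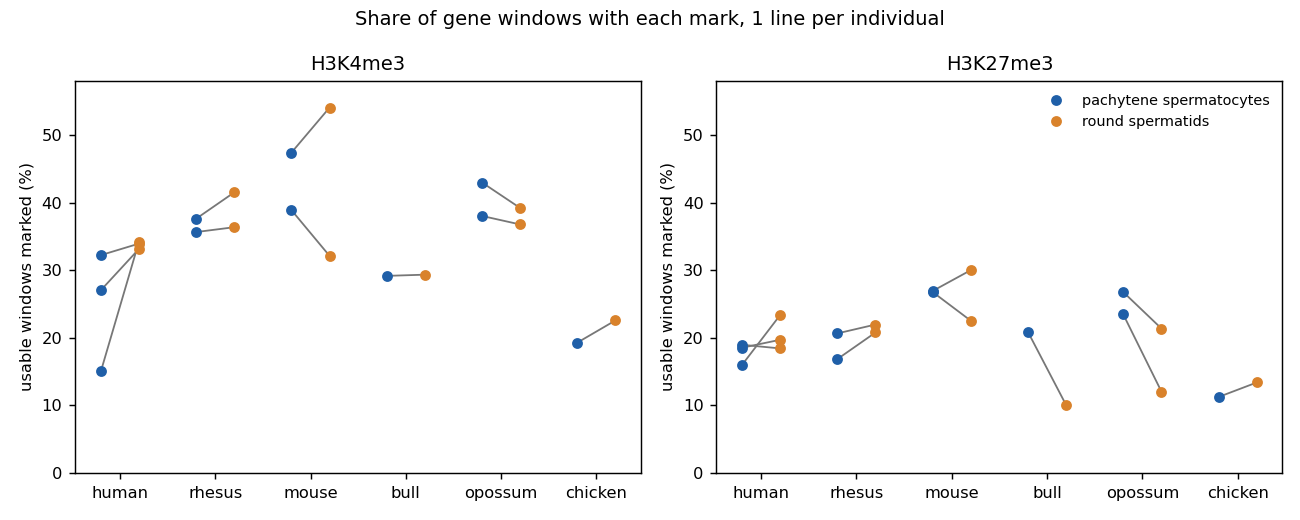
Share of usable gene windows (%) carrying H3K4me3 or H3K27me3 in each individual, with a line joining pachytene spermatocytes and round spermatids. H3K27me3 went from 23.5% to 12.04% and from 26.8% to 21.4% in the 2 opossums, and from 16.8% to 20.8% and from 20.6% to 22.0% in the 2 rhesus animals.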

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

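Of the tests in this part, the one for H3K27me3 material in a human H3K4me3 library was chosen only after the result was seen.

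Between species, 3 measures moved in opposite directions from pachytene spermatocytes to round spermatids in every individual of one species and every individual of another; the difference between species was not tested. For RNA, the median log2 change averaged 0.24 in human and 0.0497 in opossum, positive in all individuals of both, and -0.29 in rhesus, negative in both animals. These medians rest on the deposited FPKM scaling, and no test here tells a shift of all RNA from that scaling. After quantile normalization the median over all tested genes in limma was -0.04 in human, -0.07 in rhesus and 0.07 in opossum. Human and rhesus then no longer moved in opposite directions. For H3K4me3, the share of marked windows changed by 9.01 percentage points on average in human (19.2, 1.71 and 6.11 in the 3 donors) and 2.31 in rhesus, and by -2.52 in opossum. For H3K27me3, it changed by 2.63 percentage points in rhesus and by -8.40 in opossum.

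In human the H3K4me3 mean holds a donor 1 pachytene library with 15.0% of windows marked, against 32.2% and 27.04% in donors 2 and 3. Low read depth is argued against, since the other pachytene libraries thinned to its total still had 34.1% and 29.3% of windows marked. Admixture of H3K27me3 material cannot be told apart, because windows with H3K27me3 alone stood 1.20 log2 units above windows with neither mark, inside the range of the other 5 libraries (0.911 to 1.28), while windows with H3K4me3 alone stood 1.56 above them, against 2.77 to 3.32. A weaker pull-down cannot be told apart either, because the library had 46.4% of its counts in windows marked in the other 5 libraries and so lay between those libraries (60.6% to 65.1%) and the inputs (28.0% to 29.2%). Dilution with input reads, for which no prediction was written, did not reproduce it. Diluted by 49.8% and 44.2%, the pachytene libraries of donors 2 and 3 had 4.40% and 4.54% of windows marked. Their windows with H3K27me3 alone stood at 0.257 and 0.274 of the log2 height of those with H3K4me3 alone, against 0.769 here. This rests on 1 library and does not cover other forms of weak pull-down. No biological explanation was tested for a single library.

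In opossum the share of windows with H3K27me3 was lower in round spermatids of both animals, 12.04% against 23.5% and 21.4% against 26.8%. A difference between the input libraries of the stages is argued against as the whole cause, since with 1 input pooled over both stages the share still changed by -6.64 and -2.97 percentage points. With the input of each stage the changes were -11.4 and -5.39, so part of the fall went with the input. Across windows the inputs of the 2 animals correlated at 0.511 in pachytene spermatocytes and 0.640 in round spermatids (Pearson's r). A weaker pull-down in the round spermatid libraries cannot be told apart from a lower level of the mark: enrichment over windows marked in pachytene spermatocytes kept its ranking to a rho of 0.776 in animal 1 and 0.505 in animal 2, across windows, which are not independent replicates. The stage itself stays open as a biological explanation. The edgeR count of 369 windows was 0 without the pachytene library 2 (643 at an unadjusted p under 0.05) and 15 without the round spermatid library 2.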

How the results depend on the processing

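Most alternatives were fixed before the data were examined; those chosen after seeing the data are the settings that join the block with another choice (quantile normalization, the pseudocount, a left-out donor or an estimated correlation), the replicate block in list tests, protein-coding genes alone, individuals left out of the X-linked difference and of expression by mark, and leaving out the human donor 1 pachytene H3K4me3 library from the bivalent count. The cause of a change was not tested unless stated. Depth is unknown for FPKM, and H3K27me3 calls are limited by libraries of down to 1013585 counts. Of the named genes, 68 RNA genes gave 816 comparisons, 435 with the same call and 379 past the threshold where the unblocked limma fit was not, and 2 reversals, both SYCP1, whose log2 change was -0.19 without donor 2, with or without the block, and 0.42 without donor 1. The 38 H3K4me3 genes gave 481 comparisons, 340 with the same call and 141 no longer past the threshold, and the 2 H3K27me3 genes 24, with 12 and 12; those that did not reverse kept their direction. With a donor or animal's library left out from an arm of 2, the lone library is assumed to vary like the others.

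In RNA (limma), the human count of 1 gene was 2 with a pseudocount of 0.1, 0 with no filter (6431 at an unadjusted p under 0.05), 0 to 1827 with a donor left out, and 6438 with the replicate block. With the replicate block joined to quantile normalization it was 6359, to a pseudocount of 0.1 6541, and without donor 1, 2 or 3 1435, 4296 or 5964. The rhesus count of 1 was 0 with no filter (5105 at an unadjusted p under 0.05), 0 to 33 with a library left out, and 5657 with the replicate block, 3983 with quantile normalization added and 5357 with the pseudocount added. In mouse the count of 0 became 2735, 2485 and 4581 under those 3 blocked fits and stayed at 0 with a library left out (60 to 1108 at an unadjusted p under 0.05). In opossum it became 560, 721 and 591, and 0 to 12 with a library left out. In the self-test with the block, human and rhesus gave 21 false calls of 126 and 32 of 185, above the threshold of 0.05. The simulation changed far fewer genes than passed in the real data. The share of false calls among the 6438 and 5657 is therefore unknown and may lie above that threshold. In mouse the blocked self-test made 0 calls, so it gives no share of false calls for the 2735 genes.

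For H3K4me3 (edgeR) the human count of 2530 was 0 to 5167 with a library left out (0 without the donor 2 round spermatid library, 5167 without the donor 1 pachytene library), and 5051 with the replicate block and without donor 1. The rhesus count of 3851 was 2185 with RLE size factors, 6114 with library totals alone and 670 to 6060 with a library left out (670 without pachytene 1, 6060 without round spermatid 2, 1464 without pachytene 2). The mouse count of 2331 was 5332 with library totals alone, 4244 with the replicate block and 0 to 4885 with a library left out (0 without pachytene 1, 4885 without round spermatid 1, 1308 and 3775 without the pachytene and round spermatid library 2). The opossum count of 2728 was 6556 with the replicate block and 0 to 5292 with a library left out (0 without round spermatid 2, 5292 without pachytene 1, 757 without round spermatid 1, 4949 without pachytene 2).

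For H3K27me3 (edgeR) the human count of 4 was 2 with DESeq2 and 0 to 4 with a library left out. The rhesus count of 7 was 0 with RLE size factors and 0 with library totals alone (2364 and 1999 at an unadjusted p under 0.05), 100 with DESeq2, 2793 with the replicate block and 0 to 2226 with a library left out (0 without round spermatid 2, 1 without round spermatid 1, 1044 and 2226 without pachytene 1 and 2). The opossum count of 369 was 1384 with DESeq2, 1724 with the replicate block and 0 to 910 with a library left out (0 without pachytene 2, 15 without round spermatid 2, 244 without round spermatid 1, 910 without pachytene 1). The mouse count was 0 under each setting run, with 14 to 2114 windows at an unadjusted p under 0.05 in edgeR or DESeq2.

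Counts of bivalent and low genes in human, rhesus, mouse, bull, opossum and chicken were 4289, 2782, 3083, 811, 1318 and 537 with a 2-fold H3K4me3 limit, 142, 285, 222, 0, 34 and 0 with an 8-fold limit, and 946, 793, 684, 50, 288 and 10 below 1 FPKM. With no expression limit they were 2076 in rhesus, 249 in bull and 86 in chicken. A 1.5-fold H3K27me3 limit gave 657 in opossum and 62 in chicken, and a 3-fold limit 81 in bull, 189 in opossum and 5 in chicken. With an individual left out they were 1784 to 2700 in human (2700 without donor 1), 1510 to 2353 in rhesus, 1569 to 3505 in mouse and 541 to 854 in opossum, where fewer libraries must carry both marks. Protein-coding genes alone gave 109 in human, and leaving out the donor 1 pachytene H3K4me3 library gave 2266.

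The X-linked difference of 0.64 was 0.92 with a pseudocount of 0.1 and 0.19 with no filter. The log2 difference in expression between genes with both marks and with H3K4me3 alone was -2.31 in human pachytene spermatocytes with a 3-fold H3K27me3 limit. With 1.5-fold and 3-fold limits it was -1.58 and -1.88 in bull pachytene spermatocytes, -1.30 and -2.17 in bull round spermatids, -1.75 and -2.35 in opossum round spermatids, -0.85 and -0.32 in chicken pachytene spermatocytes, and -1.05 and -1.75 in chicken round spermatids.

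The camera calls of limma were all lost with an estimated correlation. For RNA the adjusted p was 0.482 for myoid, piRNA and X-linked genes and 0.629 for spermiogenesis, and with the replicate block added 0.764 for myoid and X-linked genes and 0.924 for piRNA and spermiogenesis genes. For the 9 H3K4me3 lists it was 0.574, and 0.626 with the replicate block. For the 8 H3K27me3 lists it was 0.704, or 0.439 for erythroid and meiotic genes, and 0.763 with the replicate block. The replicate block changed no other call on a list than those given here and in the report. Counts of genes bivalent in all 6 species and of genes whose stage effect differed between human and mouse were not run, because no table used here links genes between species, and the choice of window per symbol was not run outside human, where each gene has 1 identifier.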

Other observations

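Of the tests in this part, those of a general lower purity, of expression in the round spermatids themselves and of other divisions with the donor as a block were chosen only after the result was seen.

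Genes whose H3K4me3 rose between the stages in human also had higher RNA in round spermatids. Before the comparison it was put as a hypothesis that RNA of these genes rises too. Of 17964 genes tested in both assays, 1698 had risen in H3K4me3 in edgeR, and their median log2 RNA change was 1.46, 1.67 and 1.099 in the 3 donors, against 0.13, 0.17 and 0.17 for the other 16266. The lowest difference of the 3 donors was 0.93. In limma with the donor as a block 1215 of them rose in RNA (71.6%) and 8 fell, where 19.8% of the other genes rose and independent lists would share 419. Both assays used cells of the same donors, so the overlap can hold differences between preparations as well as between stages, and without the round spermatid H3K4me3 library of donor 2 edgeR called 0 windows (5519 at an unadjusted p under 0.05).

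Peritubular myoid markers were higher in human round spermatid RNA, 6 of 6 with the donor as a block. On the log2 scale the lists of other cell types did not rise alike. The myoid median lay above that of 5 of 6 other lists by a mean of more than 2 SD of the difference over donors. It lay above Sertoli genes by 1.39, 2.65 and 2.18 and above spermatogonia genes by 1.86, 1.89 and 1.36, though not above erythroid genes. This test cannot exclude a general lower purity of the round spermatid fractions. The scale understates the change of low genes, and a lower purity need not add all other cells alike. Most Sertoli and macrophage markers are near 1 FPKM or below. Over all 12 macrophage genes the median went from 0.152 ± 0.156 to 0.982 ± 0.253 FPKM, and over 6 erythroid genes from 0.259 ± 0.237 to 2.03 ± 0.629. Among the lists of other cell types only the Sertoli median fell, from 1.29 ± 0.361 to 0.869 ± 0.105. A rise of more than 1 other cell type stays open. Myoid or other stromal cells in these fractions stay open as a candidate source. Of further smooth muscle and matrix genes tested, none of them on the myoid list, 29 of 29 were higher in round spermatids. Their median change was at least 1.06 above that of all tested genes in each donor. SPARC went from 37.5 ± 9.07 to 101 ± 77.2 FPKM, IGFBP7 from 17.3 ± 1.69 to 77.7 ± 22.99 and DCN from 11.6 ± 10.8 to 72.8 ± 71.6. The labels state a purity above 95%, and the share of such cells was not measured here. Expression in the spermatids themselves stays open too, since the median H3K4me3 enrichment of the 6 marker windows in round spermatids was 2.38, 2.16 and 2.13 in the 3 donors, the lowest 2.13, against 1.56, 2.00 and 1.74 in pachytene spermatocytes. Of the windows, CNN1 went from 2.17 ± 0.48 to 3.80 ± 0.26, while ACTA2 was at 2.56 ± 0.60 and 2.50 ± 0.12 and TAGLN at 1.05 ± 0.39 and 1.06 ± 0.35.

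Human RNA levels of donor 1 stood apart from those of donors 2 and 3. Of 29 replication-dependent histone genes, which lack poly(A) tails in dividing cells, 29 were lower in donor 1 in both stages, with a median log2 difference of -2.29 in pachytene spermatocytes and -2.94 in round spermatids, against 0.19 and -0.27 between donors 2 and 3. Across genes, which are not independent replicates, Pearson's r in pachytene spermatocytes was 0.820 between donors 1 and 2, 0.785 between 1 and 3 and 0.911 between 2 and 3, and in round spermatids 0.806, 0.764 and 0.922. Without the histone genes r was 0.822, 0.787 and 0.911, and 0.808, 0.767 and 0.922. These genes therefore do not account for the lower r of donor 1. The changes between the stages did not set donor 1 apart, with r of 0.661, 0.555 and 0.516 for the same pairs.

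The 6 human libraries of each assay can be divided into groups of 3 in 10 ways, too few for a share under 0.05. For RNA the real division called 1 gene in limma and the highest other 3, and 4 of the 10 called at least as many as the real one. For H3K4me3 the real one called 2530 windows in edgeR and the highest other 0, so 1 of the 10 reached it. For H3K27me3 the real one called 4 and the highest other 19, and 5 of the 10 reached it. That highest other set both libraries of donor 1 and the round spermatid library of donor 2 against the rest. The numbers pair the libraries by donor, and in 3 other divisions each donor likewise has 1 library on each side; in the rest 1 donor is divided and the other 2 lie whole on opposite sides. Against those 3 the real division called 1 RNA gene and the highest other 0, 2530 and 0 for H3K4me3 and 4 and 1 for H3K27me3. With the donor as a block it called 6438 RNA genes, 3356 H3K4me3 windows and 3 H3K27me3 windows, and the highest of these 3 others 0 in each assay. So few divisions cannot give a share under 0.05 either. In these 3 others the stage difference adds to the residual spread, so their 0 calls do not measure false calls.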
